A study of Mus musculus with 9 samples.

How the data were processed

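Small RNA of complexes of retinal pigment epithelium (RPE, the pigmented cell layer behind the retina), choroid (the vascular layer beneath it) and sclera was sequenced from C57BL/6 mice. Per the labels, 3 complexes came from untreated mice, 3 from mice at day 3 and 3 from mice at day 7 after laser burns that disrupt Bruch's membrane, a model of choroidal neovascularization. The assay counts tRNA-derived fragments: tRFs (tRNA-derived fragments) and tiRNAs (the longer fragments made by cleavage in the anticodon loop).

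Per the labels, RNA was treated before ligation to remove bound amino acids and cyclic phosphates, to phosphorylate 5' ends and to demethylate m1A and m3C, modifications that block adapter ligation or reverse transcription. Libraries were then selected on a gel, so lengths outside the selected window are under-represented. The submitters' processing notes name FastQC, Bowtie and edgeR without versions or roles, and the mouse build mm10. The authors gave 2 values per fragment and library: counts of reads (unit: counts, raw) and CPM (unit: cpm, counts scaled by the authors to the mapped reads of each library), per the file headers. Count divided by CPM gave a single total per library, which was taken as the total of mapped reads. It exceeded the sum of the listed counts, so the table covers part of each library. In addition, 7 lines of the table were empty and were not used here. The table held 200 fragments of 14 to 40 nt. Every listed fragment reached at least 20.1 CPM in at least 1 library, so fragments below that level were not analysed here. Some items are not reported here.

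Counts were tested with edgeR 4.0.16 in R 4.3.3. Mapped totals were the library sizes, with TMM (trimmed mean of M values) factors, which ranged from 0.749 to 1.14. The filterByExpr filter removed 0 of 200 fragments. A quasi-likelihood model with a mean per group was fitted to all 9 libraries, and quasi-likelihood F tests compared day 3 with control, day 7 with control and day 7 with day 3. Tests were two-sided, with Benjamini-Hochberg adjustment over the 200 fragments and a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of F. The common biological coefficient of variation was 34.9%. Group values are means of the deposited CPM with SD and n = 3; fold changes come from the edgeR fit, so a ratio of CPM means can differ from them by the TMM factors.

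Lists of at least 5 fragments were defined by class, by the side of the tRNA, by parent isoacceptor (amino acid and anticodon), by mitochondrial origin and by length, which gave 30 lists. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. Camera compares a list with all other fragments, so a list called higher or lower is so relative to them. Shares of the listed counts were compared with two-sided exact permutation tests over the 20 assignments of 6 libraries; the smallest p that 3 against 3 allows is 0.1. The labels do not say that the complexes came from separate animals, so p-values measure only the spread between these samples, which may be technical. Replicate numbers did not pair the libraries: 2 of 9 same-number pairs had a correlation over 0.1 after group means were removed.

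Per comparison, the named fragments were the 10 higher and 10 lower with the smallest adjusted p among those that passed. Where fewer than 5 of a direction passed, the 5 with the smallest unadjusted p were named. The 5 with the highest control means and the most abundant Glu-CTC and Gly-GCC fragments were added. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, limma-voom, relative log expression (RLE) factors, mapped totals without TMM, no filter, a mean of at least 100 CPM, fits of 2 groups, a replicate block, other thresholds, overlapping fragments summed, other list tests and each library left out. Scaling to the listed counts and a fit without Gly-GCC fragments were chosen after seeing the data. The code was tested on simulated data of 200 fragments, 40 of them changed, 20 times. It recovered 93.9% of 4-fold changes and 30.3% of 2-fold changes for day 3 against control, with 6.49% of calls false. Fragments were simulated independently of each other, unlike neighbouring lengths of the same tRNA, so these rates may not hold for the real fragments.

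Sequences of 17 mitochondrial fragments were matched to transcripts of chromosome M of GRCm38, the assembly that mm10 denotes. Where the full sequence did not match, a terminal A, CA or CCA was taken off, as for the Trp-TCA and His-GTG fragments. By this rule 17 matched exactly. Nuclear tRNA genes were not located here. Of the 200 fragments, 74 matched more than 1 tRNA gene and 41 more than 1 anticodon in the deposited alignments, so their counts cannot be assigned to a single gene. Counts of the 41 cannot be assigned to a single anticodon either. Parent lists follow the anticodon in the fragment name alone, and the named Pro-AGG-1-M3 fragments, for example, match 3 anticodons. The labels name no molecular identifiers, and fold changes rest on the spread between libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.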

Results

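Fragments of tRNAs were sequenced in 9 complexes of mouse RPE, choroid and sclera: 3 untreated controls, 3 taken at day 3 and 3 taken at day 7 after laser injury. The laser breaks Bruch's membrane, the sheet between RPE and choroid, through which new choroidal vessels then grow. Mapped reads numbered 1223377, 1749792 and 2155977 in control replicates 1 to 3. They numbered 2012274, 2138312 and 1638381 at day 3, and 1204173, 1791720 and 1449949 at day 7. Correlations of log2 CPM were 0.932 to 0.972 within groups and 0.852 to 0.970 between groups. No pair of libraries agreed within sampling noise, the smallest chi-square per degree of freedom being 20.6.

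The 200 listed fragments fell into the classes used in this field. There were 121 tRF-5 fragments, which start at the 5' end of the mature tRNA (29 tRF-5a, 9 tRF-5b and 83 tRF-5c, by increasing length), and 25 tiRNA-5, which run from the 5' end to the anticodon loop. The 34 tRF-3 fragments, which end at the mature 3' end, comprised 28 tRF-3a and 6 tRF-3b, and there were 3 tiRNA-3, which run from the anticodon loop to the 3' end. A further 16 were listed as tRF-1, the class from the 3' trailer of the precursor tRNA; of these, tRF-+1:T27-chrM.Gly-TCC lies at 9459 to 9485 on chromosome M (GRCm38), inside the protein-coding gene mt-Nd3 (9459 to 9806). The last 1 was tRF-2, from around the anticodon. Fragment names give the first and last nucleotide and the parent tRNA; in tRF-1 names, T precedes the last nucleotide of the trailer.

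Fragments of tRNA Gly-GCC dominated every group. They held 95.2% ± 0.396 of the listed counts in the controls, 92.5% ± 1.05 at day 3 and 95.8% ± 0.790 at day 7 (SD, n = 3; exact permutation p = 0.1 for day 3 against control and p = 0.3 for day 7 against control). The 5 most abundant control fragments were 5' fragments of Gly-GCC tRNAs. The most abundant, tRF-1:31-Gly-GCC-2-M3 (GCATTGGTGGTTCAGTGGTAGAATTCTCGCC), averaged 491419 ± 10659 CPM in the controls, 324613 ± 8480 at day 3 and 440861 ± 74030 at day 7 (SD, n = 3). It alone held 64.8% ± 1.47, 55.2% ± 2.02 and 57.1% ± 8.44 of the listed counts. The others were its 30 nt, 32 nt and 33 nt forms, at 101954 ± 14041, 90629 ± 10400 and 13349 ± 2451 CPM, and tRF-1:31-Gly-GCC-1 at 13643 ± 1144 CPM. The listed fragments together held 75.8% ± 0.179 of mapped reads in the controls, 58.8% ± 3.05 at day 3 and 77.0% ± 1.67 at day 7 (exact permutation p = 0.1 for day 3 against control and p = 0.4 for day 7).

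The first comparison asked which fragments differed at day 3 after laser. At day 3, 43 of 200 fragments changed, 20 higher and 23 lower than in the controls (edgeR, adjusted p below 0.05). Among these calls the direction mostly followed the side of the tRNA. All 20 that rose were 5'-derived. Of the 23 that fell, 14 were 3'-derived, 5 were tRF-1, 3 were 5'-derived and 1 was tRF-2. In the 10 named fragments that rose, each day 3 library lay above each control library; they were chosen by the test of these same libraries, so this adds no separate evidence.

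The 5' fragments that rose came from several parent tRNAs. The 29 nt fragment tRF-1:29-Gly-GCC-1 went from 199 ± 60.4 CPM in the controls to 988 ± 420 at day 3, a log2 fold change of 2.31 (SE 0.438, adjusted p = 0.00271). The 32 nt fragment tRF-1:32-Gly-CCC-2 went from 77.5 ± 12.7 to 282 ± 99.5 CPM (log2 fold change 1.81), and its 33 nt neighbour tiRNA-1:33-Gly-CCC-2 from 49.5 ± 4.66 to 161 ± 83.6 CPM (1.66). Fragments of 32 nt also rose for Val-CAC-1 (log2 fold change 1.76), Pro-AGG-1-M3 (1.44), Glu-TTC-3 (1.42) and Glu-CTC-2 (1.39). The Glu-TTC-3 and Glu-CTC-2 sequences are close, and base errors in reads were not tested for them, so they may not be separate support. Short 16 nt fragments rose for Gly-TCC-1 (2.50) and Ala-CGC-3-M3 (2.12). The mitochondrial fragment tRF-1:29-chrM.Ser-GCT rose from 3.63 ± 1.31 to 24.5 ± 10.5 CPM (2.72, adjusted p = 0.0112). It lies at 11613 to 11641 on the plus strand of chromosome M (GRCm38), in the tRNA gene mt-Ts2, which spans 11613 to 11671 and encodes a mitochondrial serine tRNA. With a library left out, 4 of these fragments missed the threshold and kept their direction. Without day 3 replicate 2 the log2 fold change was 2.32 for tRF-1:29-chrM.Ser-GCT (adjusted p = 0.0587), 1.03 for the Pro-AGG-1-M3 fragment (0.0583) and 1.35 for the Ala-CGC-3-M3 fragment (0.138). Without control replicate 3 it was 1.37 for Pro-AGG-1-M3 (0.0676) and 2.15 for Ala-CGC-3-M3 (0.0574), without control replicate 1 it was 1.83 for Ala-CGC-3-M3 (0.0843), and without control replicate 2 it was 1.32 for the 32 nt Glu-CTC-2 fragment (0.0545).

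The Gly-GCC-1 and Gly-GCC-2-M3 fragments differ at a single base, T5G (position 5 from the 5' end, Gly-GCC-2-M3 base first). Summed over 28 to 33 nt, Gly-GCC-1 counts were 2.63% ± 0.191 of Gly-GCC-2-M3 counts in the controls, 7.15% ± 1.44 at day 3 and 3.49% ± 0.369 at day 7 (SD, n = 3; exact permutation p = 0.1 for each of the 3 comparisons). This ratio of counts in the same library does not depend on the scaling of libraries. The abundant tRF-1:31-Gly-GCC-2-M3 itself had a log2 fold change of -0.64 at day 3 (adjusted p = 0.0811), and tRF-1:31-Gly-GCC-1 of 0.80 (adjusted p = 0.0847).

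**Figure D1:**
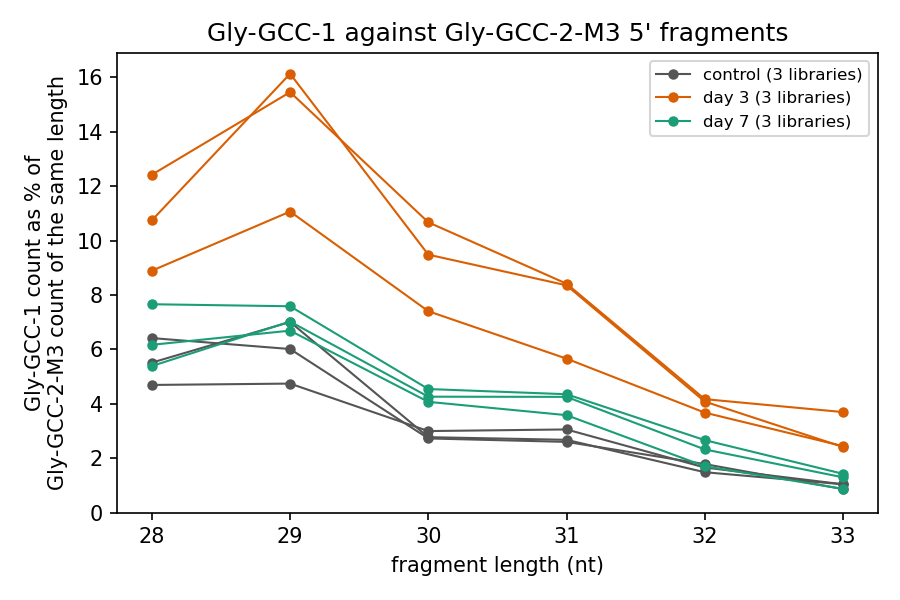
Counts of Gly-GCC-1 fragments as a percent of Gly-GCC-2-M3 fragments of the same length (vertical axis) against fragment length in nt (horizontal axis), with 1 line per library. At each length the 3 day 3 libraries lay above the 3 control libraries.

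The fragments that fell at day 3 were mostly from the 3' side of the tRNA or from the precursor trailer. The 22 nt fragment tRF-54:75-Ala-CGC-1-M2, which ends in the CCA of the mature 3' end, went from 66.9 ± 7.36 to 16.9 ± 7.57 CPM (log2 fold change -2.04, SE 0.374, adjusted p = 0.00271). Fragments of 17 or 18 nt from the 3' ends of tRNA Leu, Cys and Gly fell as well: tRF-68:85-Leu-AAG-1-M4 from 167 ± 17.5 to 50.1 ± 9.50 CPM (-1.78), tRF-59:75-Cys-GCA-2-M4 from 46.4 ± 7.30 to 11.9 ± 4.43 CPM and tRF-57:74-Gly-CCC-2-M6 from 26.7 ± 3.47 to 7.00 ± 1.23 CPM (-1.95). Trailer fragments of Thr-CGT-1 of 30, 31 and 32 nt had log2 fold changes of -1.92, -1.99 and -2.11, and those of Arg-ACG-1-3 of 22 and 23 nt had -1.77 and -2.01. The tRF-2 fragment tRF-30:43-Gln-CTG-1-M5 fell on few counts: it had 1, 3 and 1 counts at day 3 and 6, 82 and 3 in the controls. Its log2 fold change of -4.24 rested on control replicate 2: without that library it was -1.81 with an adjusted p of 0.233, and under limma-voom the adjusted p was 0.0739.

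The lists, tested on the same libraries, were divided by side as well. The 5'-derived list holds 146 of the 200 fragments, so its test against the others largely restates those of the 3'-derived and tRF-1 lists. In other splits of these 6 libraries up to 15 lists passed, against 10 in the real split. The small p-values with the preset correlation are therefore no separate evidence. Of 146 5'-derived fragments 20 rose, 3 fell and 123 did not pass (camera adjusted p = 1.7e-15; adjusted p = 0.0219 with an estimated correlation); adjusted over the list alone, 16 rose and 3 fell. Of 83 tRF-5c fragments 15 rose and 2 fell (adjusted p = 3.7e-06), and the same counts held adjusted over the list alone. Of 29 tRF-5a fragments 4 rose (2 adjusted over the list alone; adjusted p = 0.0150). Of 94 fragments of 30 nt or more 13 rose and 5 fell (12 and 5 adjusted over the list alone; adjusted p = 0.0150). With an estimated correlation the adjusted p was 0.419, 0.529 and 0.509 for these last 3 lists. Not every 5' class rose. Of 25 tiRNA-5 fragments 1 rose and 0 fell, with 10 above 0 and 15 below (camera adjusted p = 0.830). Of 9 tRF-5b fragments 0 rose and 1 fell (camera adjusted p = 0.913).

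Of 37 3'-derived fragments 14 fell and 0 rose (21 fell adjusted over the list alone; camera adjusted p = 1.7e-08). Within them, 10 of 28 tRF-3a (13 adjusted over the list alone; adjusted p = 8.2e-05) and 3 of 6 tRF-3b fell (6 adjusted over the list alone; adjusted p = 0.00207). Of 16 tRF-1 fragments 5 fell, also adjusted over the list alone (adjusted p = 8.6e-05), and 16 had a log2 fold change below 0. These 5 were neighbouring lengths of the Thr-CGT-1 and Arg-ACG-1-3 trailers alone, so they are not independent (estimated correlation 0.641 over the list). The Arg-ACG-1-3 trailers were also the 2 that fell in the Arg-ACG list. Arg-ACG (2 of 5 lower, 3 adjusted over the list alone; adjusted p = 0.0150) and lengths of 18 to 22 nt (9 of 26 lower, 13 adjusted over the list alone; adjusted p = 3.3e-05) also passed. With an estimated correlation these 6 lists had adjusted p = 0.419 (3'-derived, and 18 to 22 nt), 0.509 (tRF-3a and tRF-3b) and 0.529 (tRF-1 and Arg-ACG). With fry, a rotation test of limma, 6 of the 10 lists that passed missed the threshold: tRF-1 (adjusted p = 0.0974), tRF-5a (0.176), tRF-5c and 5'-derived (0.0988 each), Arg-ACG (0.0540) and 30 nt or more (0.225). With libraries left out, Arg-ACG missed it without control replicate 1 (camera adjusted p = 0.0691), 30 nt or more without day 3 replicate 1 (0.144) and tRF-5a without day 3 replicate 3 (0.0934). No direction changed in these fits. The other 20 lists did not pass. Among them were Gly-GCC (2 of 16 rose, 8 higher and 2 lower adjusted over the list alone; adjusted p = 0.196), Lys-CTT (4 of 9 rose, 4 higher and 1 lower adjusted over the list alone; adjusted p = 0.140) and mitochondrial fragments (1 of 17 rose and 3 fell, 1 and 5 adjusted over the list alone; adjusted p = 0.632). In 7 of the 20 the median, the mean and the test differed in sign.

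The median directions of the 10 lists that passed kept their sign under each scaling that was tried, while the number of single fragments depended on the scaling. Scaling to the listed counts, chosen after seeing the data, moved the median log2 fold change by 0.41 and gave 49 higher and 14 lower. Under it 49 of the 146 5'-derived fragments rose and 2 fell, 6 of the 37 3'-derived fell and 5 of the 16 tRF-1 fell. Leaving out control replicate 3 left 22 calls and leaving out day 3 replicate 2 left 25. A filter at a mean of 100 CPM, which kept 70 fragments, gave 18 higher and 4 lower, and a fit of the 2 groups alone gave 67 calls.

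The second comparison asked which fragments differed at day 7 after laser. At day 7, 8 of 200 fragments changed, and the 7 that rose were 32 and 33 nt fragments from the 5' end of glycine tRNAs. In each of the 7, every day 7 library lay above every control library, as the choice by the test of these libraries favours. The 33 nt fragment of Gly-CCC-1 had a log2 fold change of 0.09 (adjusted p = 0.954), and the 32 nt fragments of Gly-CCC-1, Gly-CCC-3-M2 and Gly-TCC-1 had 1.13, 0.95 and 0.43 without passing; these 4 were named after their values were seen. At an unadjusted p below 0.05 there were 38 fragments.

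The 7 that rose came from Gly-CCC and Gly-GCC tRNAs, which no test compared; over all members the median log2 fold change was 0.05 for Gly-CCC and 0.15 for Gly-GCC. The 33 nt tiRNA-1:33-Gly-CCC-2 (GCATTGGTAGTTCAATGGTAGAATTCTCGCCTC) went from 49.5 ± 4.66 CPM in the controls to 220 ± 102 at day 7 (SD, n = 3; edgeR log2 fold change 2.36, SE 0.433, adjusted p = 0.00223), and the 32 nt form from 77.5 ± 12.7 to 288 ± 106 CPM (2.11). The 33 nt tiRNA-1:33-Gly-CCC-3-M2, at 109 ± 37.1 CPM at day 7, had a log2 fold change of 1.95. For Gly-GCC-1, the 33 nt fragment went from 130 ± 18.3 to 382 ± 118 CPM (1.81) and the 32 nt fragment from 1477 ± 31.4 to 4145 ± 1900 CPM (1.71). For Gly-GCC-2-M3, the 33 nt fragment went from 13349 ± 2451 to 31833 ± 5742 CPM (1.53, SE 0.320) and the 32 nt fragment from 90629 ± 10400 to 182518 ± 68261 CPM (1.22, SE 0.280). The 30 nt and 31 nt forms of Gly-GCC-2-M3 had log2 fold changes of -0.54 (adjusted p = 0.462) and 0.17 (adjusted p = 0.841; -0.16 with mapped totals without TMM and -0.18 when scaled to the listed counts).

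In the 4 parents of the 7 fragments that rose, chosen for those calls, 32 and 33 nt took a larger share of the counts of 30 to 33 nt at day 7. The share went from 14.9% ± 1.05 to 30.5% ± 11.4 for Gly-GCC-2-M3, from 8.89% ± 0.578 to 18.5% ± 8.95 for Gly-GCC-1, from 22.3% ± 2.98 to 49.6% ± 13.5 for Gly-CCC-2 and from 18.2% ± 3.00 to 37.8% ± 9.35 for Gly-CCC-3-M2. In each of the 4 parents every day 7 library lay above every control library (exact permutation p = 0.1, the smallest that 3 against 3 allows), which the choice of parents favours. Their sequences are close, Gly-GCC-1 and Gly-GCC-2-M3 fragments differing by T5G alone, and base errors in reads were not tested for this pattern. The 4 parents may therefore not be separate support. Among 19 parents with both length ranges, the log2 ratio of 32 and 33 nt to 30 and 31 nt counts was lower at day 7 than in the controls in 3: Gly-TCC-1 (difference -0.20), Glu-TTC-1 (-0.05) and Glu-TTC-2 (-0.02). At day 3 the share was 20.3% ± 3.88 for Gly-GCC-2-M3, and for the next 3 parents in that order it exceeded the controls by 2.72, 17.7 and 9.60 percentage points (exact permutation p = 0.1, 0.3, 0.1 and 0.1). Day 7 and day 3 overlapped in each of the 4 parents (exact permutation p from 0.2 to 0.4). When the median of that ratio over 13 parents other than glycine was taken off in each library, every day 7 library stayed above every control library in 1 of the 4 parents, Gly-CCC-2 (corrected log2 difference 1.29, against 0.63 for Gly-GCC-1, 0.95 for Gly-CCC-3-M2 and 0.78 for Gly-GCC-2-M3). This correction was chosen after the result was seen.

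**Figure D2:**
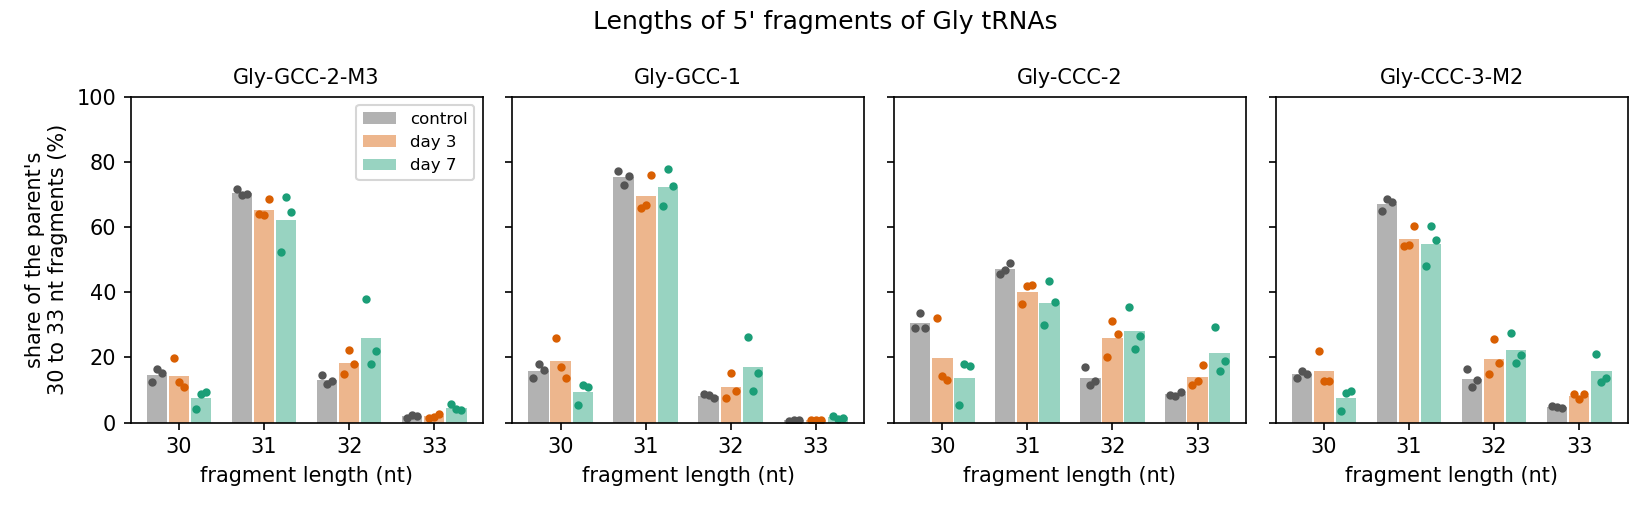
Share of each length among the 30 to 33 nt 5' fragments of 4 glycine tRNAs (vertical axis, percent) against fragment length in nt (horizontal axis), with bars for group means and points for the 3 libraries of each group. For Gly-CCC-2, 32 and 33 nt together went from 22.3% in the controls to 49.6% at day 7.

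The fragment that fell at day 7 was tiRNA-1:34-Asp-GTC-2, a 34 nt fragment of an aspartate tRNA, from 32.4 ± 4.67 to 9.20 ± 1.40 CPM (log2 fold change -1.52, SE 0.367, adjusted p = 0.0119). The 4 next in order of p did not pass: 30 nt Pro-AGG-1-M3 (log2 fold change -1.23, adjusted p = 0.0741), and 30 nt Glu-CTC-2 (-1.46), 32 nt Glu-TTC-2 (-1.07) and 30 nt Glu-TTC-3 (-1.13), each at adjusted p = 0.111. Of the 30 lists, 1 passed: Glu-TTC was lower (camera adjusted p = 0.00121; adjusted p = 0.703 with an estimated correlation and 0.183 with fry), with 14 of 17 members below 0 and 0 past the threshold singly, also adjusted over the list alone. At an unadjusted p its members 32 nt Glu-TTC-2 and 30 nt Glu-TTC-3 had 0.00790 and 0.00793 in edgeR. The other 29 lists did not pass, including Gly-GCC (4 of 16 rose, 4 adjusted over the list alone; adjusted p = 0.264), Gly-CCC (3 of 14 rose, 5 adjusted over the list alone; adjusted p = 0.264) and mitochondrial fragments (0 of 17, also adjusted over the list alone; adjusted p = 0.129). In 4 of the 29 the median, the mean and the test differed in sign.

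The number of day 7 calls varied with the control libraries. There were 17 without control replicate 1, 3 without control replicate 2 and 5 without control replicate 3. Without control replicate 2 the log2 fold change was 1.69 for the 33 nt Gly-GCC-1 fragment and 1.49 for the 33 nt Gly-GCC-2-M3 fragment (adjusted p = 0.0612 for both), 1.55 for the 32 nt Gly-GCC-1 fragment (0.0783), 1.01 for the 32 nt Gly-GCC-2-M3 fragment (0.211) and -1.61 for tiRNA-1:34-Asp-GTC-2 (0.0711). Without control replicate 3 it was 1.68 for the 32 nt Gly-GCC-1 fragment (0.0606), 1.18 for the 32 nt Gly-GCC-2-M3 fragment (0.0901) and -1.47 for tiRNA-1:34-Asp-GTC-2 (0.0873). The last also missed the threshold without day 7 replicate 1 (-1.40, adjusted p = 0.0707) and under limma-voom (-1.50, adjusted p = 0.0671). The list count was 4 without control replicate 1, 6 without day 7 replicate 1 and 4 without day 7 replicate 2. Other scalings moved the median log2 fold change by -0.13 (RLE), -0.26 (mapped totals without TMM) and -0.28 (listed counts); the 7 higher calls stood at 7 in each, beside 2, 7 and 8 lower.

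The share of listed counts in fragments that the table lists as tiRNAs was 3.86% ± 0.591 in the controls, 3.81% ± 1.18 at day 3 and 5.87% ± 1.37 at day 7 (SD, n = 3). The 32 nt Gly-GCC-2-M3 fragment is listed as tRF-5c and its 33 nt form as tiRNA-5. This share therefore does not measure all cleavage in the anticodon loop. The difference was -0.0463 percentage points for day 3 against control (exact permutation p = 1), 2.01 for day 7 against control (exact permutation p = 0.1) and 2.06 for day 7 against day 3 (exact permutation p = 0.2). With libraries left out, day 7 against control ranged from 1.23 to 2.47 points and day 7 against day 3 from 1.27 to 2.73. Both were lowest without day 7 replicate 1. Adjusted over the classes, the p for day 7 against control was 0.367 (exact permutation). Without tRF-1:31-Gly-GCC-2-M3, the most abundant fragment, the differences were -2.32, 2.72 and 5.04 points (exact permutation p = 0.4, 0.1 and 0.1). The tRF-5c class took 95.3% ± 0.559, 95.2% ± 1.34 and 93.3% ± 1.49. The day 3 difference turned positive in 4 fits with a library left out: 0.216 points without control replicate 2, 0.0117 without control replicate 3, 0.165 without day 3 replicate 1 and 0.408 without day 3 replicate 2. Mitochondrial fragments, the one inside mt-Nd3 included, took 0.250% ± 0.0753, 0.367% ± 0.0817 and 0.350% ± 0.138 of listed counts (exact permutation p = 0.3 and p = 0.4 against control). The tRF-3a class took 0.208% ± 0.0268, 0.176% ± 0.0520 and 0.173% ± 0.0593, with no return at day 7. Its exact permutation p was 0.4 for day 3 against control and 0.9 for day 7 against day 3. In the same order, tRF-3b took 0.0329%, 0.0147% and 0.0209% (exact permutation p = 0.1 and 0.5). The tRF-1 class took 0.0979%, 0.0644% and 0.114% (exact permutation p = 0.3 and 0.2), and tRF-5a 0.238%, 0.418% and 0.216% (0.1 and 0.1).

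The third comparison tested directly whether day 7 differed from day 3. Between these times 69 of 200 fragments differed, 46 higher and 23 lower at day 7. Of 16 tRF-1 fragments 12 were higher at day 7, and of 37 3'-derived fragments 18 were (adjusted p = 0.459 for both lists with an estimated correlation). Lengths of the same trailer are counted separately here. When scaled to the listed counts, 9 fragments of any class were higher at day 7, so these class counts depend on the scaling. Of the 20 fragments that had risen at day 3, 7 were lower at day 7 than at day 3, and of the 23 that had fallen, 21 were higher. Both tests use the day 3 libraries, so such reversals are favoured by chance.

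Trailer fragments of Arg-ACG-1-3 were higher at day 7: the 23 nt form went from 7.27 ± 0.703 CPM at day 3 to 34.4 ± 17.2 at day 7 (log2 fold change 2.46, SE 0.412, adjusted p = 0.000684), with 28.9 ± 8.72 in the controls, and the 22 nt form had 2.32. The 3' fragments tRF-54:75-Ala-CGC-1-M2 and tRF-68:85-Leu-AAG-1-M4 had log2 fold changes of 1.89 and 1.51. Among mitochondrial tRNAs, tRF-54:70-chrM.Trp-TCA (17 nt; mt-Tw, chromosome M, 5003 to 5016, with CCA added) had 2.21, and the tiRNA-3 fragments of mt-Th (chromosome M, 11576 to 11612), which encodes the histidine tRNA, had 2.06 at 40 nt and 2.33 at 38 nt. Their 39 nt form, named after its values were seen, had 1.69 (adjusted p = 0.0248), with 4.97, 3.27 and 10.4 CPM in the day 3 libraries and 14.9, 8.37 and 23.4 in those of day 7, which overlap. The deposited CPM of the 40 nt form overlapped between day 3 and day 7 as well. The 33 nt and 32 nt Gly-GCC-2-M3 fragments had 2.04 and 1.26, tiRNA-1:33-Gly-CCC-3-M2 had 1.41, and tRF-30:43-Gln-CTG-1-M5 had 4.37, with 22, 24 and 22 counts at day 7 against 1, 3 and 1 at day 3. The abundant tRF-1:31-Gly-GCC-2-M3 had 0.81 (adjusted p = 0.0254), a call lost in 12 of 14 alternatives, for example with RLE factors (adjusted p = 0.0997, over a range of 0.000401 to 0.848).

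Among fragments lower at day 7 than at day 3, tRF-1:29-Gly-GCC-1 went from 988 ± 420 to 174 ± 16.1 CPM (log2 fold change -2.17, SE 0.437, adjusted p = 0.00258). Fragments of 30, 31 and 32 nt of Glu-TTC-3 had log2 fold changes of -1.75, -1.79 and -1.27, and those of Glu-CTC-2 of 31 and 32 nt had -1.83 and -1.53. These parents are close in sequence and may not be separate support. The 31 nt Glu-CTC-2 fragment averaged 127 ± 14.6, 286 ± 47.2 and 59.4 ± 32.9 CPM in controls, day 3 and day 7. The 30 nt Pro-AGG-1-M3 fragment had -1.78, the 34 nt Asp-GTC-2 fragment -1.71, and the 16 nt fragments of Leu-AAG-2-M3 and Leu-CAG-1-M3 had -1.58 and -1.36.

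Of the 30 lists, 12 passed, 7 higher and 5 lower at day 7 than at day 3, relative to the other fragments. The 5'-derived list holds most of the fragments, so its result largely mirrors the 3'-derived and tRF-1 lists. Its own median log2 fold change was -0.17. Higher were tRF-1 (12 of 16 members, 13 adjusted over the list alone; camera adjusted p = 5.0e-05), 3'-derived fragments (18 of 37, also over the list alone; adjusted p = 0.000275), tRF-3a (12 of 28, also over the list alone; adjusted p = 0.0113), Arg-ACG (5 of 5, also over the list alone; adjusted p = 0.00267), His-GTG (4 of 8, also over the list alone; adjusted p = 0.0113), tiRNAs (8 of 28 higher and 1 lower, also over the list alone; adjusted p = 0.0195) and 18 to 22 nt (13 of 26, also over the list alone; adjusted p = 0.00334). Lower were 5'-derived fragments (15 higher and 23 lower of 146, also over the list alone; adjusted p = 1.3e-09), tRF-5c (6 higher and 19 lower of 83, also over the list alone; adjusted p = 4.6e-06), tRF-5a (2 higher and 3 lower of 29, also over the list alone; adjusted p = 0.0195), Glu-TTC (4 lower of 17, also over the list alone; adjusted p = 0.0120) and Pro-AGG (2 lower of 6, 3 adjusted over the list alone; adjusted p = 0.0398). With an estimated correlation the adjusted p was 0.0892 for 5'-derived, 0.500 for tRF-3a, 0.461 for tRF-5a and 0.459 for the other 9 lists. With fry, 5'-derived (0.364), tRF-5a (0.253), tRF-5c (0.115) and Glu-TTC (0.0664) missed the threshold. With libraries left out, Pro-AGG and tiRNAs missed it without day 3 replicate 2 (camera adjusted p = 0.0859 and 0.0667) and without day 7 replicate 3 (0.167 and 0.0535), tRF-5a without day 3 replicate 3 (0.0729) and without day 7 replicate 1 (0.106), and His-GTG without day 3 replicate 3 (0.0508). Pro-AGG also missed it with mapped totals without TMM (0.0585). In 2 of the 18 that did not pass, the median, the mean and the test differed in sign.

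The division into higher and lower depended on the scaling: 46 and 23 with TMM, 37 and 35 with RLE factors, 30 and 39 with mapped totals without TMM, and 9 and 63 when scaled to the listed counts, which moved the median log2 fold change by -0.65 (-0.22 for RLE and -0.27 without TMM). In the last, tRF-68:85-Leu-AAG-1-M4 and the 32 nt Gly-GCC-2-M3 fragment missed the threshold (adjusted p = 0.107 and 0.0506). Calls numbered 45 without day 3 replicate 1, 39 without day 3 replicate 2 and 44 without day 7 replicate 1.

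The day 3 and day 7 comparisons share the control libraries, which by itself makes their fold changes correlate. Over the 200 fragments, which are not independent replicates, the correlation of the log2 fold changes was 0.261, against 0.507 (0.364 to 0.668) in 100 simulations with no change other than the shared controls. The observed covariance was 0.201 and the simulated 0.106. Fragments that rose in both comparisons numbered 3, tRF-1:32-Gly-GCC-1, tRF-1:32-Gly-CCC-2 and tiRNA-1:33-Gly-CCC-2, and those that fell in both numbered 0. The simulations gave 0 fragments that rose in both (0 to 0). They held no change at either time, so they do not show how many shared controls give where each time has changes of its own, and with 3 controls the libraries could not be split between the comparisons. The simulations also drew each fragment independently, so their range of 0.364 to 0.668 may be too narrow.

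**Figure D3:**
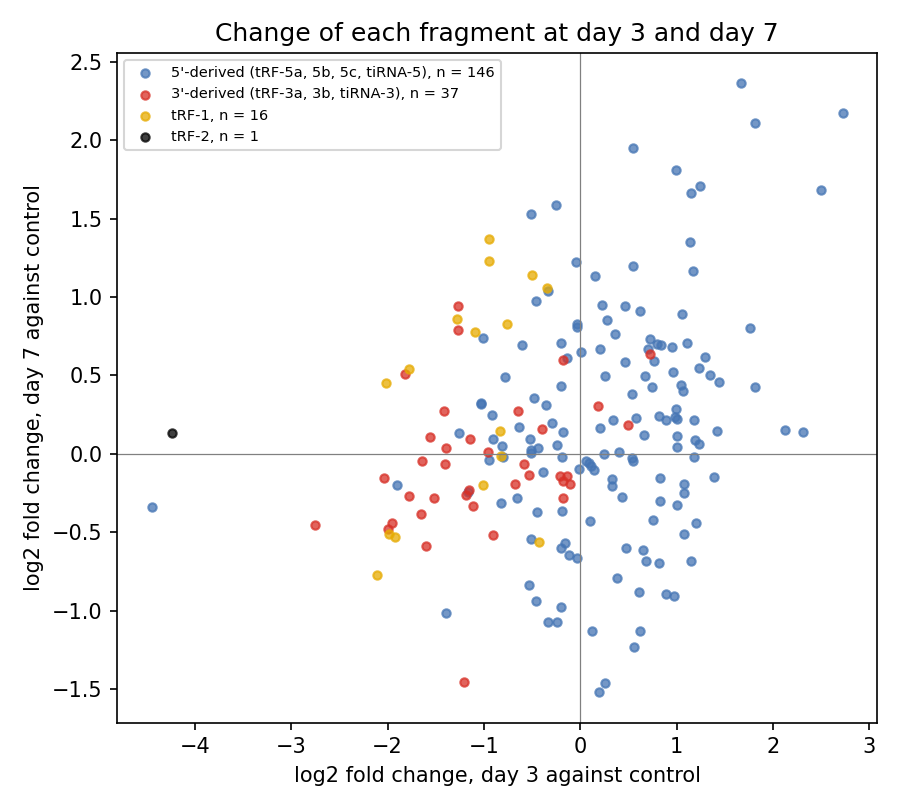
Log2 fold change against control at day 7 (vertical axis) against that at day 3 (horizontal axis), with 1 point per fragment, coloured by the side of the tRNA: 146 5'-derived, 37 3'-derived, 16 tRF-1 and 1 tRF-2. Of 37 3'-derived fragments 34 lay below 0 at day 3, and 16 of 16 tRF-1 did.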

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

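The tests of the calls, of libraries left out and of other splits of the libraries were planned; the other tests in this part, which weigh explanations for 3 patterns, were chosen after the results were seen. The response differed between the times: 69 fragments differed between day 7 and day 3 in a direct test, 1 of 10 splits of these 6 libraries gave as many and the highest of the other splits gave 1. Against control, day 3 gave 43 calls (1 of 10 splits as many, highest other 0) and day 7 gave 8 (1 of 10, highest other 0). For lists the real values were 10, 1 and 12 for day 3, day 7 and day 7 against day 3, and the highest of the other splits 15, 8 and 12, with 5, 10 and 2 of 10 splits as large. With 10 splits a share under 0.05 cannot be reached.

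Fragments lower at day 7 than at day 3 (log2) were tRF-1:29-Gly-GCC-1 (-2.17), tRF-1:16-Ala-CGC-3-M3 (-1.97), Glu-CTC-2 of 30, 31 and 32 nt (-1.72, -1.83 and -1.53), Glu-TTC-3 of 30, 31 and 32 nt (-1.75, -1.79 and -1.27), tRF-1:30-Pro-AGG-1-M3 (-1.78), tiRNA-1:34-Asp-GTC-2 (-1.71), tRF-1:16-Leu-AAG-2-M3 (-1.58) and tRF-1:16-Leu-CAG-1-M3 (-1.36). Those higher were Gly-GCC-2-M3 of 31, 32 and 33 nt (0.81, 1.26 and 2.04), tiRNA-1:33-Gly-CCC-3-M2 (1.41), Thr-CGT-1 trailers of 30, 31 and 32 nt (1.39, 1.48 and 1.34), Arg-ACG-1-3 trailers of 22 and 23 nt (2.32 and 2.46) and 3' fragments of Gly-CCC-2-M6 (1.51), Leu-AAG-1-M4 (1.51), Cys-GCA-2-M4 (1.52) and Ala-CGC-1-M2 (1.89). The mitochondrial tiRNA-3 fragments of His-GTG had 2.06 at 40 nt, 1.69 at 39 nt and 2.33 at 38 nt. In deposited CPM the day 3 and day 7 libraries of the 40 nt and 39 nt forms overlapped. The fragment tRF-54:70-chrM.Trp-TCA had 2.21, and tRF-30:43-Gln-CTG-1-M5 had 4.37, with 1 to 3 counts per library at day 3. The call of the 31 nt Gly-GCC-2-M3 fragment was lost in 12 of 14 alternatives. Mapped reads outside the listed fragments took 41.2% at day 3 against 24.2% in the controls; what they hold was not analysed here.

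At day 3, 14 of 37 3'-derived and 5 of 16 tRF-1 fragments fell and 20 of 146 5'-derived fragments rose, with 52 of the 146 below 0 (6, 5 and 49 when scaled to the listed counts). With an estimated correlation the lists had camera adjusted p = 0.419, 0.529 and 0.0219. As shares of listed counts, tRF-3a and tRF-1 overlapped between day 3 and control (exact permutation p = 0.4 and 0.3), while tRF-3b did not (0.1). A single scaling factor per library is argued against by mean log2 CPM of 3'-derived and tRF-1 fragments less that of 5'-derived fragments, which no factor moves. It was -1.11 ± 0.241 in the controls and -2.41 ± 0.396 at day 3, a difference of -1.30. Fragment length is argued against too, for 35 of the 53 3'-derived and tRF-1 fragments. Their median log2 difference from 5'-derived fragments within 1 nt of their length was -1.53. The others had no 5'-derived fragment of such a length and were not tested. Amino acids left on 3' ends are argued against for tRF-1, which carry none (median log2 fold change -0.98, 16 of 16 below 0). These 16 include several lengths of the same trailers and are not independent (estimated correlation 0.641). That explanation stays open for the 3'-derived part, where 0 of 37 sequences lack a terminal CCA. In tiRNA-32:69-chrM.His-GTG-M1-37:C>A and tiRNA-32:70-chrM.His-GTG-M1-38:C>A part of that CCA matched the gene, with only A and CA added, and they were not tested apart. A change in tRNA cleavage or processing after injury may contribute; it was not tested, and the cell content of the tissue at day 3 was not measured here.

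At day 7, 7 fragments of 32 and 33 nt from 4 glycine parents rose, while the Gly-GCC and Gly-CCC lists did not pass (adjusted p = 0.264 for both). A scaling factor multiplies all lengths of a library alike and cannot move the share of 32 and 33 nt within a parent. It is argued against, because in 4 of the 4 parents with calls that share was larger in each day 7 library than in each control library. The choice of these parents for their calls leaves open how far the rise exceeds noise. The 4 parents are close in sequence and base errors in reads were not tested for this pattern, so they may not be separate support. A single day 7 library as the sole source is argued against, since at least 7 of the 7 calls stayed with any of them left out. Day 7 replicate 1 still had the largest 32 nt share in each of the 4 parents, so the size of the rise leans on it. Selection of longer inserts stays open, also as the whole cause. The mean edgeR log2 fold change of the 32 and 33 nt fragments of a parent less that of its 30 and 31 nt fragments had a median of 1.47 in 6 glycine parents, grouped after the calls were seen, and 0.54 (SD 0.394) in 13 others, 12 of them above 0. The ranges overlapped, with 0.07 for Gly-TCC-1, 1.21 for Pro-AGG-1-M3 and 1.16 for Glu-TTC-3. The ratio of summed counts, a second calculation, weights abundant fragments more and gave -0.20 for Gly-TCC-1, -0.05 for Glu-TTC-1 and -0.02 for Glu-TTC-2. The medians were compared first and read as evidence against selection; a correction of the ratio of summed counts per library, made later, replaced that reading. With the median of those 13 parents taken off in each library, the separation of day 7 from control stayed in 1 of the 4 parents with calls (Gly-CCC-2, corrected difference 1.29), so a shift of insert length may account for the pattern. A change in where glycine tRNAs are cleaved is also open and was not tested.

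At day 3, Gly-GCC-1 fragments gained on Gly-GCC-2-M3 fragments, which differ by T5G (position 5 from the 5' end). A fixed rate of base errors in reads of the far more abundant fragment is argued against as the source of all Gly-GCC-1 counts within the controls, where the ratio at 29 nt was at least 4.56 times that at 33 nt. An error rate that differs between libraries stays open. It would add the same amount to the ratio at every length, so the excess over the ratio at 33 nt would not move; the lowest day 3 excess was 1.16 to 2.54 times the highest control excess at 28 to 31 nt, but 0.517 times at 32 nt, where the groups overlapped. This test replaced a comparison of the ratio itself, which restated the pattern. Greater cleavage or abundance of the Gly-GCC-1 tRNA after laser may explain the gain, as an untested hypothesis.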

How the results depend on the processing

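The alternatives of scaling to the listed counts and of leaving out Gly-GCC fragments were chosen after seeing the data. Of 923 values of named fragments under an alternative, 844 kept their direction and side of the threshold, 33 lost a call, 31 gained one and 15 changed sign. For day 3 against control (43 calls) there were 22 at a mean of at least 100 CPM (70 fragments tested), 67 with only the 2 groups compared, 88 at an unadjusted p under 0.05 and a fold of at least 1.5, and 83 at an adjusted p under 0.1; libraries left out gave 22 to 54. For day 7 against control (8 calls) there were 15 with DESeq2, 14 with mapped totals without TMM, 15 scaled to listed counts, 4 without Gly-GCC fragments (184 tested), 5 with overlapping fragments summed (121 tested) and 38 at an unadjusted p; libraries left out gave 3 to 17. For day 7 against day 3 (69 calls) there were 31 at a mean of at least 100 CPM and 45 with overlapping fragments summed; libraries left out gave 39 to 72. A replicate block gave 47, 8 and 64 calls, and the numbers did not pair the libraries. What moved these counts was not tested.

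List counts for day 3 (10) were 1 with an estimated correlation and 5 with fry; for day 7 (1) they were 0 and 0, and 1 to 6 with libraries left out; for day 7 against day 3 (12) 0 with an estimated correlation. The difference in tiRNA share at day 3 (-0.0463 points) ranged from -0.711 to 0.408 with libraries left out and was -2.32 without the most abundant fragment, which also gave 5.04 for day 7 against day 3 (2.06); that at day 7 against control (2.01) was -0.0235 as a share of fragments detected, where nearly all are detected. For tRF-1:32-Gly-GCC-2-M3 at day 3 (log2 -0.04) the sign changed with DESeq2 (0.0297), RLE factors (0.0297), mapped totals (0.00798), the 100 CPM filter (0.0708) and listed counts (0.380), over -0.22 to 0.13 with libraries left out. For tRF-1:31-Gly-GCC-2-M3 at day 7 (0.17) it changed with mapped totals (-0.16) and listed counts (-0.18), over -0.00785 to 0.43 with libraries left out. With libraries left out, day 7 against day 3 ranged from -0.31 to 0.37 for tRF-1:30-Gly-GCC-2-M3 (-0.03) and from -0.30 to 0.14 for tRF-1:31-Gly-GCC-1 (-0.10). The cause was not tested. The filter for low counts removed 0 fragments, so that alternative tested nothing, and the pseudocount alternative was not run because the values are counts. In simulations of independent fragments 30.3%, 24.5% and 27.0% of 2-fold changes were recovered in the 3 comparisons, so absence of a call does not show absence of such a change.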

Other observations

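The test of insert length reported here was chosen after the result was seen. In 11 parents with both a 34 nt tiRNA-5 and a 32 nt fragment, the share of 34 nt in their sum was compared between day 3 and control. In 5 each day 3 library lay below each control library and in 0 each lay above. These were Lys-CTT-3 (68.1% ± 8.10 to 31.1% ± 9.77, n = 3), Glu-CTC-2 (64.7% to 45.6%), Ala-CGC-5 (62.1% to 47.6%), Lys-TTT-1 (86.5% to 76.9%) and Lys-CTT-2 (98.5% to 91.5%). The 6 others overlapped, among them Glu-TTC-1 (88.9% to 91.2%), Glu-TTC-2 (89.8% to 89.5%) and Glu-TTC-3 (96.7% to 95.3%). At day 7, 7 of 11 parents had each library above each day 3 library and 1 below. Lower recovery of inserts over 33 nt at day 3 may contribute and stays open: with the median log2 ratio of 34 to 32 nt over the parents taken off in each library, 1 parent lay wholly above the controls and 4 wholly below. The 1 above, Asp-GTC-1-M2, was itself the median parent in each day 3 library, so its place was partly set by the correction. This test replaced a count of mean shares, in which 3 of 11 parents were higher at day 3 while overlapping the controls.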
